A study of Mus musculus with 9 samples.

How the data were processed

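Poly-A RNA of sorted monocytic myeloid-derived suppressor cells from MC38 tumours was sequenced in 9 libraries, 3 each from WT, LILRB4+/+ and LILRB4+/+ SCG2-/- mice. The kit kept the strand, per the labels' protocols. Reads were handled with HISAT2 2.0.5 and featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Gene coordinates in the tables matched the GRCm38 reference annotation at both ends for 53585 of the 54495 gene identifiers found there (98.3%), so positions are quoted on GRCm38. The labels do not say what the LILRB4 allele is, which gate was used for sorting, or which mouse each library came from, so p-values measure the spread between these samples, which may be technical.

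The authors deposited raw counts per gene for 9877 genes and FPKM values for 54532 genes with each gene's length. The authors' FPKM values, multiplied by gene length and 1 constant per library, gave whole numbers for 100% of values within a tolerance of 0.01, and these are called recovered counts. The FPKM denominators were proportional to size factors of the recovered counts, with a largest deviation of 2.08e-10%. The deposited count table held protein-coding genes with 100 or more counts in LILRB4 replicates 1 and 3. All 9876 protein-coding genes that met this rule in the recovered counts were in it. It held 1 more gene, S100a8, at 115 counts in LILRB4 replicate 1 against 5 recovered counts. The table therefore left out 810 protein-coding genes with a mean recovered count of 100 or more in WT or SCG2 knockout libraries, which favours genes expressed in LILRB4 libraries. Spreadsheet software had turned 17 gene symbols of the count table and 27 of the FPKM table into dates, and genes were followed by identifier.

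The count table and the recovered counts were not the same for 56 of the 88893 values compared (99.9% were equal), in 47 genes. Of these values 41 lay in LILRB4 replicate 1, 5 in WT replicate 2, 3 in each other LILRB4 library, and 2 each in SCG2 knockout replicates 1 and 2. In 7 genes (Arg1, Stat3, Ccl9, Lyn, Il1r2, Tgfbr1 and Cox5a) 14 values were exchanged between 2 libraries. Of the other 42 values, 37 were apart by a multiple of 1000, 4 by a multiple of 100 and 1 by a multiple of 10. The files do not say how these differences arose, nor which table holds the intended values. The FPKM denominators deviated by at most 2.08e-10% with the recovered counts and by 0.0971% with the count table values put in. At these values the count table therefore departs from the quantification behind the FPKM. Gene tests and gene-list tests were computed from both, while the simulations, the splits and the alternatives other than those on FPKM or recovered counts used the deposited counts alone. The deposited counts are the main values because they were named as such before the data were examined. A gene among the 47 is said to rise or fall only where both sources passed the test. Numbers of list members adjusted over the list alone are from the deposited counts and can include such genes.

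Totals of the count table were 14501163 to 27219202 per library, and those of the recovered counts 15004944 to 28070495. A count of 0 allows up to 3 counts, which is 0.107 to 0.200 CPM, a limit that covers counting error only. No column of per-sample values was left unused. No 2 libraries of a group were duplicates, since at most 0.466% of genes had equal counts in any pair.

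Deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by the filterByExpr function with a minimum count of 10, which kept all 9877, libraries were scaled by TMM factors, and a robust quasi-likelihood model was fitted to all 9 libraries with 6 residual degrees of freedom. The comparisons were LILRB4 against WT, SCG2 knockout against LILRB4, and SCG2 knockout against WT. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and "edgeR adjusted p" stands for this quasi-likelihood test with this adjustment. Standard errors are those of log2 fold changes. The same model on recovered counts of all genes tested 15743 genes. Results with recovered counts are from this fit unless the same genes are named. A gene with the same counts in both tables can therefore lose its call there. Gene lists fixed before the data were examined were tested against all other genes with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Lists with fewer than 3 tested genes were not tested, leaving 30. On simulated counts of the 9877 genes, the LILRB4 against WT fit recovered 16% of genes changed 1.5-fold, 64% of those changed 2-fold and 96% of those changed 3-fold. The SCG2 knockout against LILRB4 fit recovered 18%, 70% and 94%. In these simulations 50 genes changed at each fold and genes varied independently at the fitted dispersions. They held no structure shared by genes across libraries, so these shares need not hold for the real data.

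Genes named for their fold changes follow a rule set before the data were examined, while genes named for table differences or outside the count table were chosen after. It takes Scg2, Lilrb4a, Lilrb4b (listed as Lilr4b), Il6, Il6ra, Il6st, Stat3, Socs3, Arg1 and Nos2 in every case. It adds the 10 largest rises and the 10 largest falls past the threshold among genes with a proper symbol, a mean log2 CPM of 1 or more and no overlap between groups, and up to 4 members past the threshold of each list. Where a direction had fewer than 5 such genes, the 5 with the smallest p are named as not passing. Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE factors, a filter at 1 CPM in 3 libraries, no filter, limma-trend on log2 of FPKM plus 1 or 0.1 for genes with an FPKM of 1 or more in 3 libraries, the replicate number as a block, each comparison's libraries alone, and each library left out in turn. The recovered counts, the omission of the 47 genes and a covariate of T and NK cell marker level were added after seeing the data, as were DESeq2 runs on 20 simulations with no effect.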

Results

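Monocytic myeloid-derived suppressor cells (M-MDSCs), monocyte-like cells that restrain T cells, were sorted from tumours of MC38, a mouse colon carcinoma line. Their poly-A RNA was profiled in 9 libraries, 3 from WT mice, 3 from LILRB4+/+ mice (LILRB4 libraries) and 3 from LILRB4+/+ SCG2-/- mice (SCG2 knockout libraries). The deposited counts summed to 18936566, 23471040 and 18676591 in WT replicates 1 to 3, 17175759, 24401452 and 27219202 in LILRB4, and 17740597, 16407643 and 14501163 in SCG2 knockout. The series title concerns SCG2 binding to LILRB4, the suppressive function of these cells and IL-6 signalling through STAT3.

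The 2 deposited tables disagreed for 47 genes, and several of these belong to the pathway in the title. Il6, Stat3, Arg1, Tnf, Il10, Il1b, Tgfb1 and Nos2 were among them. The LILRB4 to WT ratio was higher in the count table than in the counts recovered from FPKM for 44 of the 47 genes and lower for 2, and the SCG2 knockout to LILRB4 ratio was lower for 45. Arg1, which encodes arginase 1, stood at 26183 counts in LILRB4 replicate 1 and 15191 in SCG2 knockout replicate 1 in the count table, and the recovered counts held these 2 values the other way round. Stat3 had the same exchange between LILRB4 replicate 2 and SCG2 knockout replicate 2, with 14978 and 9195 counts in the count table. Fold changes from both sources are given for such genes.

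**Figure D1:**
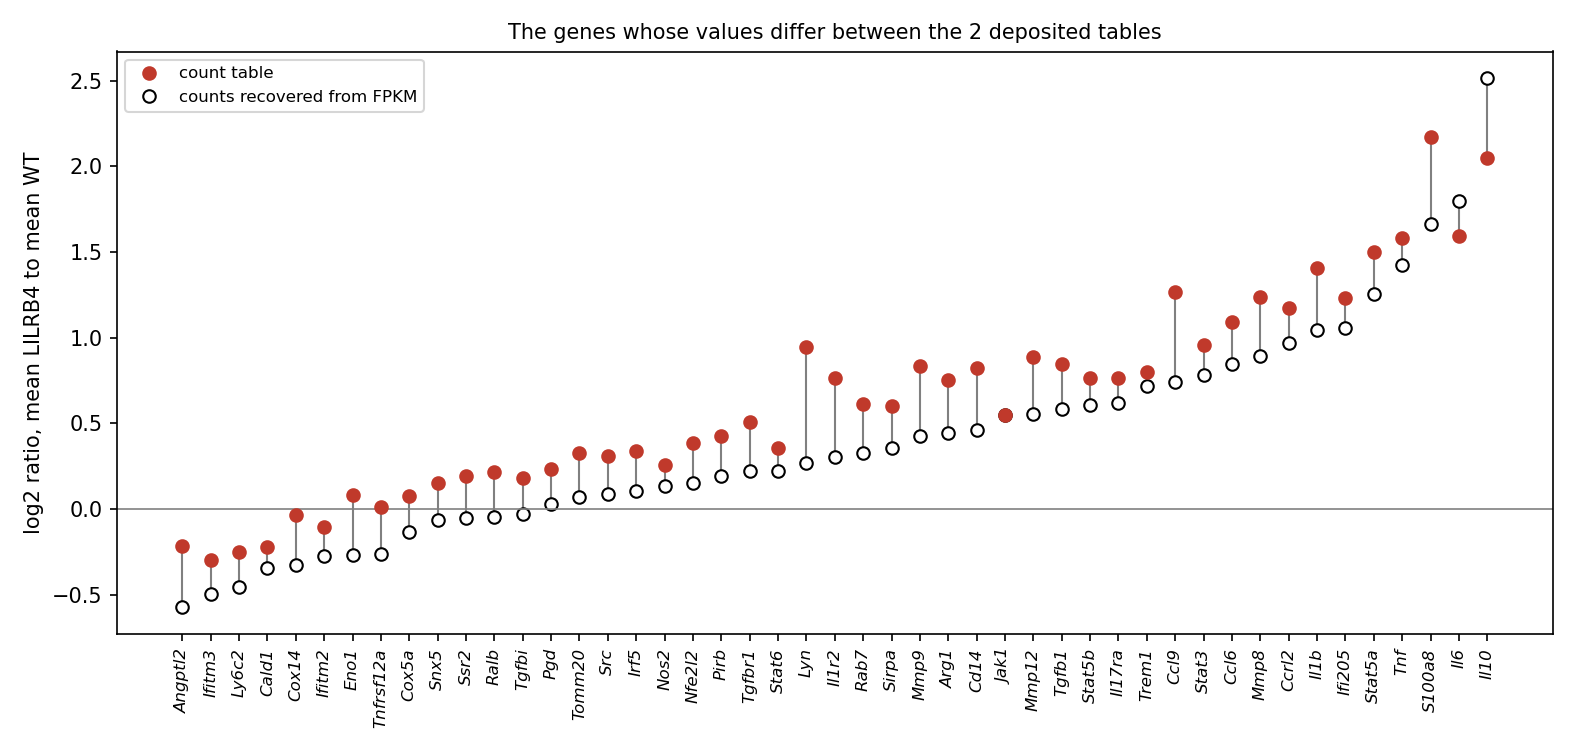
Log2 ratio of the mean LILRB4 to the mean WT value for the 47 genes that differ between the deposited tables, from the count table (filled) and from counts recovered from FPKM (open). The filled point lies above the open one for 44 genes and below it for 2, Il6 and Il10.

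Scg2, the gene removed in the knockout (ENSMUSG00000050711, chromosome 1, 79434669 to 79440120), was not detectable at this depth in any group. Its recovered count was 1 in WT replicate 1 and 1 in LILRB4 replicate 1, and 0 in the other 7 libraries, so the knockout labels could not be checked with it. Lilrb4a (ENSMUSG00000112148, chromosome 10, 51490956 to 51496611) stood at 473 ± 264 CPM in WT, 1043 ± 363 in LILRB4 and 801 ± 81.1 in SCG2 knockout libraries (mean ± SD, n = 3 each). Its neighbour and near copy Lilr4b (ENSMUSG00000112023, chromosome 10, 51480632 to 51486703) stood at 1091 ± 504, 2621 ± 893 and 2019 ± 78.2 CPM, and reads may be split unevenly between these genes. Neither passed the test in LILRB4 against WT, at log2 fold changes of 1.14 (SE 0.37, edgeR adjusted p = 0.115) and 1.27 (SE 0.33, edgeR adjusted p = 0.0652).

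LILRB4 against WT asks what the LILRB4 genotype changes in these cells. The largest rises with the count table included genes of cytokines and of a chemokine. Csf3, which encodes the neutrophil growth factor G-CSF (chromosome 11, 98701263 to 98703629), rose from 12.1 ± 1.70 to 88.2 ± 38.3 CPM (log2 2.87, SE 0.44), and Cxcl3, a neutrophil-attracting chemokine, rose from 296 ± 71.2 to 1373 ± 586 CPM (log2 2.21, SE 0.39; mean ± SD, n = 3 each). The cytokine genes Il12a, Il23a and Il1a rose by 2.09, 2.03 and 1.99 on the log2 scale (SE 0.40, 0.37 and 0.34). Slc7a11, a cystine transporter, rose by 1.64 (SE 0.24) and Ptgs2, which encodes cyclooxygenase 2, rose 2.82-fold (log2 SE 0.23). Cdk5r1, Serpinb2 and Samd11 rose by 1.93, 1.92 and 1.86 (SE 0.24, 0.27 and 0.26). Of the genes in the series title, Il6 rose by 1.57 on the log2 scale with the count table (SE 0.25, edgeR adjusted p = 0.0224) and by 1.78 with recovered counts (SE 0.28, edgeR adjusted p = 0.0242). Stat3 did not pass, at 0.92 (SE 0.27, edgeR adjusted p = 0.0851) with the count table and 0.77 (edgeR adjusted p = 0.222) with recovered counts. Socs3, a feedback inhibitor of STAT3, had a log2 fold change of 1.13 (SE 0.25, edgeR adjusted p = 0.0467) with the count table. Its counts are the same in both tables. With recovered counts of all genes Socs3 stood at 1.139 and did not pass (edgeR adjusted p = 0.0574). Arg1 did not pass with either, at 0.72 (edgeR adjusted p = 0.136) and 0.43 (edgeR adjusted p = 0.574), nor did Nos2 at 0.23 and 0.12, Il6ra at -0.01 or Il6st at 0.08.

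Among the lower genes, 4 passed both with the count table and with recovered counts of all 15743 genes tested. Cdkn2c, a cyclin-dependent kinase inhibitor, fell from 32.7 ± 4.43 to 17.0 ± 1.40 CPM (log2 -0.94, SE 0.16, edgeR adjusted p = 0.0233). The mitotic kinase gene Aurka and the cyclin gene Ccna2 fell by 0.91 (SE 0.17) and 0.83 (SE 0.15) on the log2 scale, and Idi1, of cholesterol synthesis, by 0.86 (SE 0.16). The other largest log2 differences in this direction were Ube2c at -1.02, Ly6c1 (a member of the fixed monocyte list) at -1.02, Depdc1a at -1.01, Tcf19 at -0.93, Nusap1 at -0.92, Ptk7 at -0.90, Kif2c at -0.87 and Spire2 at -0.87. They passed with the count table (edgeR adjusted p = 0.0323 to 0.0456) and not with recovered counts of all genes (edgeR adjusted p = 0.0511 to 0.0670). Their counts are the same in both tables, and their recovered log2 fold changes were -1.01 (Ube2c) to -0.85 (Spire2). In all, 171 genes were higher and 51 lower of 9877 tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. With recovered counts of 15743 genes, 128 were higher and 9 lower, of which 116 and 4 were shared with the count table. DESeq2 called 612 higher and 312 lower, and limma on log2(FPKM + 1) 91 and 11.

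The numbers of genes higher in LILRB4 than WT and of genes lower in LILRB4 than WT rested on single libraries. No gene passed in either direction without WT replicate 2 or without WT replicate 3. Without WT replicate 1 the counts were 27 higher and 5 lower, without LILRB4 replicate 1 they were 8 and 0, and without LILRB4 replicate 3 they were 14 and 0. Without LILRB4 replicate 2 they were 541 and 148. Leaving out SCG2 knockout replicate 2, which shares the estimate of spread, gave 57 and 1, and leaving out its replicates 1 or 3 gave 29 or 30 lower genes.

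**Figure D2:**
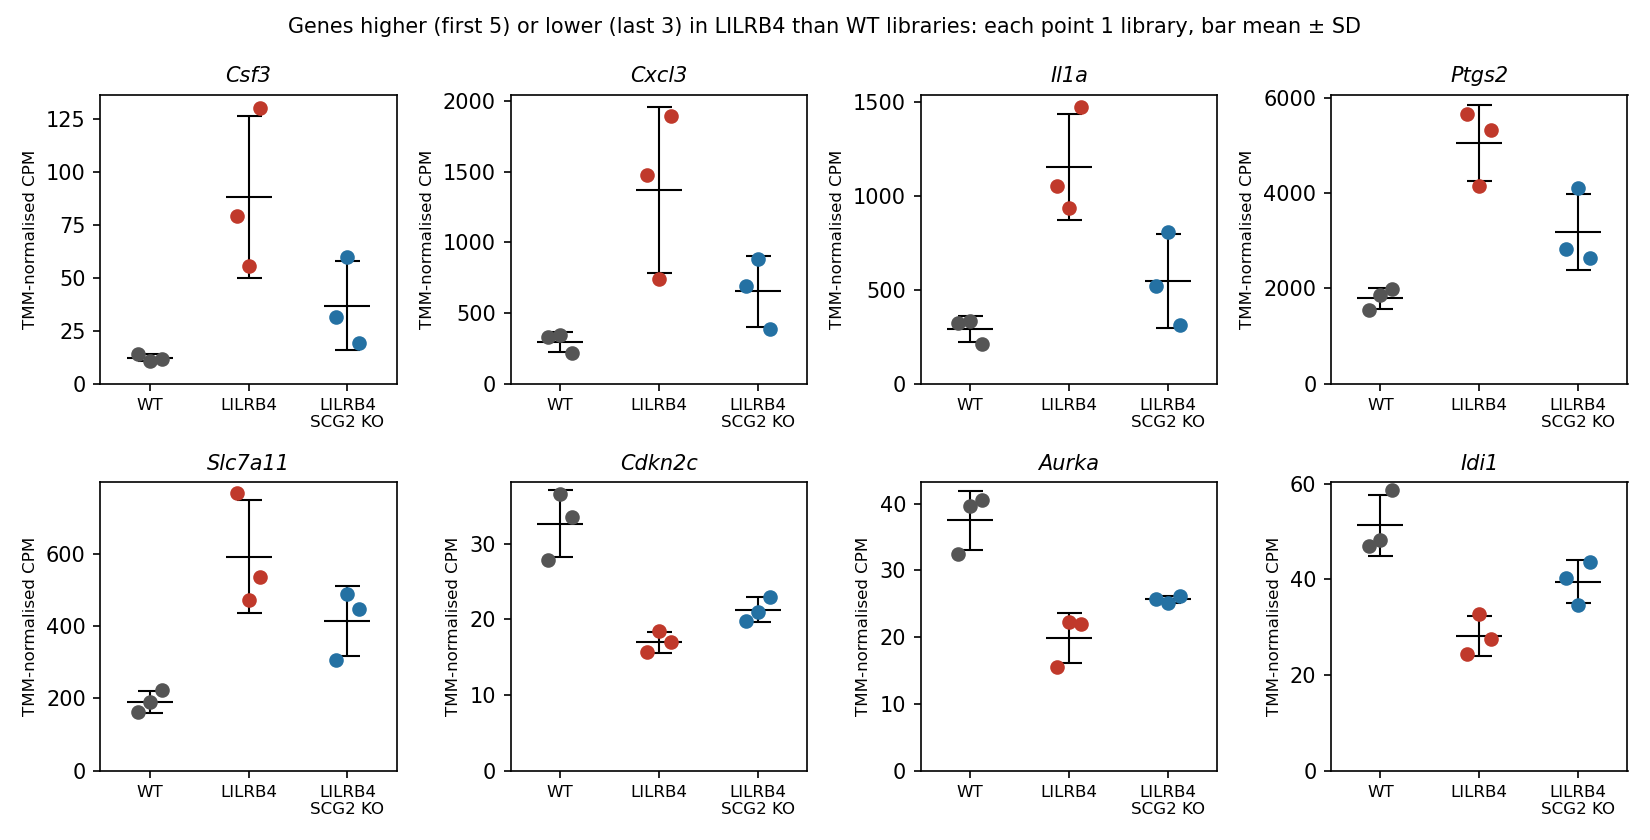
TMM-normalised CPM from the count table for 8 genes in 3 WT, 3 LILRB4 and 3 SCG2 knockout libraries, each point 1 library, with the mean and SD of each group. Csf3 averaged 12.1 CPM in WT and 88.2 in LILRB4 libraries, and Cdkn2c 32.7 and 17.0.

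NF-kB inflammatory genes had more members past the threshold in LILRB4 against WT than any other list. Of 29 measured members 14 passed the test, all upward (28 adjusted over the list alone), with a median log2 fold change of 1.17. Cxcl2, a neutrophil chemokine, rose by 1.76 (SE 0.28), and Tnf by 1.55 (SE 0.25) with the count table and 1.41 (edgeR adjusted p = 0.0399) with recovered counts. The list stood above other genes by camera (adjusted p = 1.24e-30), a call lost with an estimated correlation (adjusted p = 0.168 with an estimated correlation). In the same libraries the summed T and NK cell markers stood at 849 ± 605 CPM in WT, 1876 ± 1290 in LILRB4 and 2542 ± 605 in SCG2 knockout, and ranged from 429 to 2908 CPM among the LILRB4 libraries. Mitochondrially encoded mRNAs, at 8653 ± 1901, 14240 ± 4399 and 8050 ± 2826 CPM, and neutrophil markers, at 321 ± 59.0, 448 ± 73.4 and 262 ± 33.4 CPM, were also highest on average in LILRB4 libraries. Of 24 chemokine and receptor genes 5 passed upward (8 adjusted over the list alone), among them Cxcl1 at 1.39 (SE 0.29), while Ccrl2, at 1.14 (SE 0.20), stood at 0.96 with recovered counts and did not pass there (edgeR adjusted p = 0.0694). That list had a camera adjusted p of 1.14e-07, and an adjusted p = 0.187 with an estimated correlation.

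Suppressive effectors of MDSCs had 4 of 23 measured members past the threshold (12 adjusted over the list alone), with a median log2 fold change of 0.51. Slc7a11 and Ptgs2 are the members that passed with both tables. Il10 at 2.01 and Tgfb1 at 0.81 with the count table stood at 2.50 and 0.57 with recovered counts, where neither passed (edgeR adjusted p = 0.0656 and 0.146). Of these 23 genes 6 differ between the tables. The camera adjusted p was 4.26e-09, and the call was lost with an estimated correlation (adjusted p = 0.168 with an estimated correlation). Of 17 genes of the IL-6 receptor and JAK-STAT3 list 4 passed upward (7 up and 1 down adjusted over the list alone), namely Il6, Lifr at 0.96 (SE 0.18), Socs3 and the kinase gene Jak2 at 0.91 (SE 0.21). With recovered counts 2 of 18 passed, Il6 and Lifr, while Socs3 and Jak2, with the same counts in both tables, did not. Its camera adjusted p was 0.000427, and the adjusted p = 0.168 with an estimated correlation. STAT3 target genes had 2 of 28 past the threshold (10 up and 2 down adjusted over the list alone), Il10 and Socs3, and 0 of 30 with recovered counts. Their camera adjusted p was 6.86e-05, and the adjusted p = 0.199 with an estimated correlation. Of 11 LILRB4 signalling partners 2 passed (5 adjusted over the list alone), Traf6 at 0.70 and Nfkb1 at 1.17. Neither did with recovered counts of all genes, though the counts of both are the same in the 2 tables. The camera adjusted p of that list was 0.000768, and the adjusted p = 0.168 with an estimated correlation. Its summed level was 13330 CPM in LILRB4 replicate 2, against 7927 and 7067 in the other LILRB4 libraries and 5928 to 6376 in WT, and its median of 0.49 was 0.37 without that library.

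Of 32 cell cycle genes 8 passed downward in LILRB4 against WT (31 adjusted over the list alone), with a median log2 fold change of -0.65. The camera adjusted p was 2.32e-20, and the call was lost (adjusted p = 0.187 with an estimated correlation). Summed fibroblast markers moved alongside, at 5577 ± 393 CPM in WT, 4328 ± 533 in LILRB4 and 5632 ± 722 in SCG2 knockout libraries, beside 3319 ± 423, 2299 ± 275 and 2824 ± 113 for the cell cycle genes. Besides Aurka and Ccna2, the replication genes Mcm5 at -0.77 (SE 0.15) and Rrm2 at -0.73 (SE 0.14) passed with the count table. Cholesterol biosynthesis genes had 3 of 21 past the threshold (10 adjusted over the list alone), Idi1, Lss at -0.71 and Dhcr7 at -0.84, and a median of -0.46. The camera adjusted p was 1.26e-09, and the adjusted p = 0.253 with an estimated correlation. Only Idi1, Aurka, Ccna2 and Cdkn2c among the 51 lower genes passed as well with recovered counts of all genes, adjusted over 15743. None of the 51 differs between the tables, so their own counts do not account for the lost calls. Fewer than 51 genes were also lower with recovered counts of the same genes, and without the genes that differ between the tables. The larger number of genes tested therefore need not be the whole reason.

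Neutrophil markers had 2 of 7 past the threshold (4 adjusted over the list alone), Hdc, the histamine-forming enzyme gene, at 1.26 (SE 0.20) and Retnlg at 1.97 (SE 0.40). Retnlg, with the same counts in both tables, stood at 1.99 with recovered counts of all genes and did not pass (edgeR adjusted p = 0.0597). Their camera adjusted p was 0.000427, and the adjusted p = 0.168 with an estimated correlation. Matrix remodelling genes had 1 of 20 past the threshold (8 adjusted over the list alone), Mmp12 at 0.86, which stood at 0.54 with recovered counts (edgeR adjusted p = 0.160). Their camera adjusted p was 3.83e-05, and the adjusted p = 0.199 with an estimated correlation. No member passed of the T and NK cell markers (22 of 22 higher, median 1.08), endothelial markers (median 1.30), mitochondrially encoded mRNAs (median 0.72, 1 adjusted over the list alone), interferon-gamma response genes (median -0.33), fibroblast markers (median -0.27) and oxidative phosphorylation genes (median -0.15). These 6 lists passed camera at the preset correlation, with adjusted p of 0.000965, 0.0101, 0.00460, 0.00331, 0.0171 and 0.0309. All 6 calls were lost (adjusted p = 0.685, 0.543, 0.543, 0.573, 0.573 and 0.779 with an estimated correlation).

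The other 14 of the 30 lists did not pass in LILRB4 against WT. The dendritic cell marker Xcr1 rose by 1.69 (SE 0.32) and the glycolysis gene Hk2 by 0.76 (SE 0.15). Bhlhe40 of the hypoxia list, at 0.72 and with the same counts in both tables, did not pass with recovered counts of all genes (edgeR adjusted p = 0.0599). Median log2 fold changes were 0.78 for dendritic cell markers, -0.32 for type I interferon genes, -0.06 for MHC class I, -0.09 for glycolysis, -0.19 for hypoxia, 0.07 for fatty acid oxidation and 0.09 for the unfolded protein response. They were -0.03 for ribosomal proteins, 0.28 for mast cell and 0.25 for colon carcinoma epithelial markers. Median, mean and test differed in sign for MHC class II (median -0.10), dissociation genes (0.04), monocyte markers (0.11) and macrophage markers (-0.01).

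**Figure D3:**
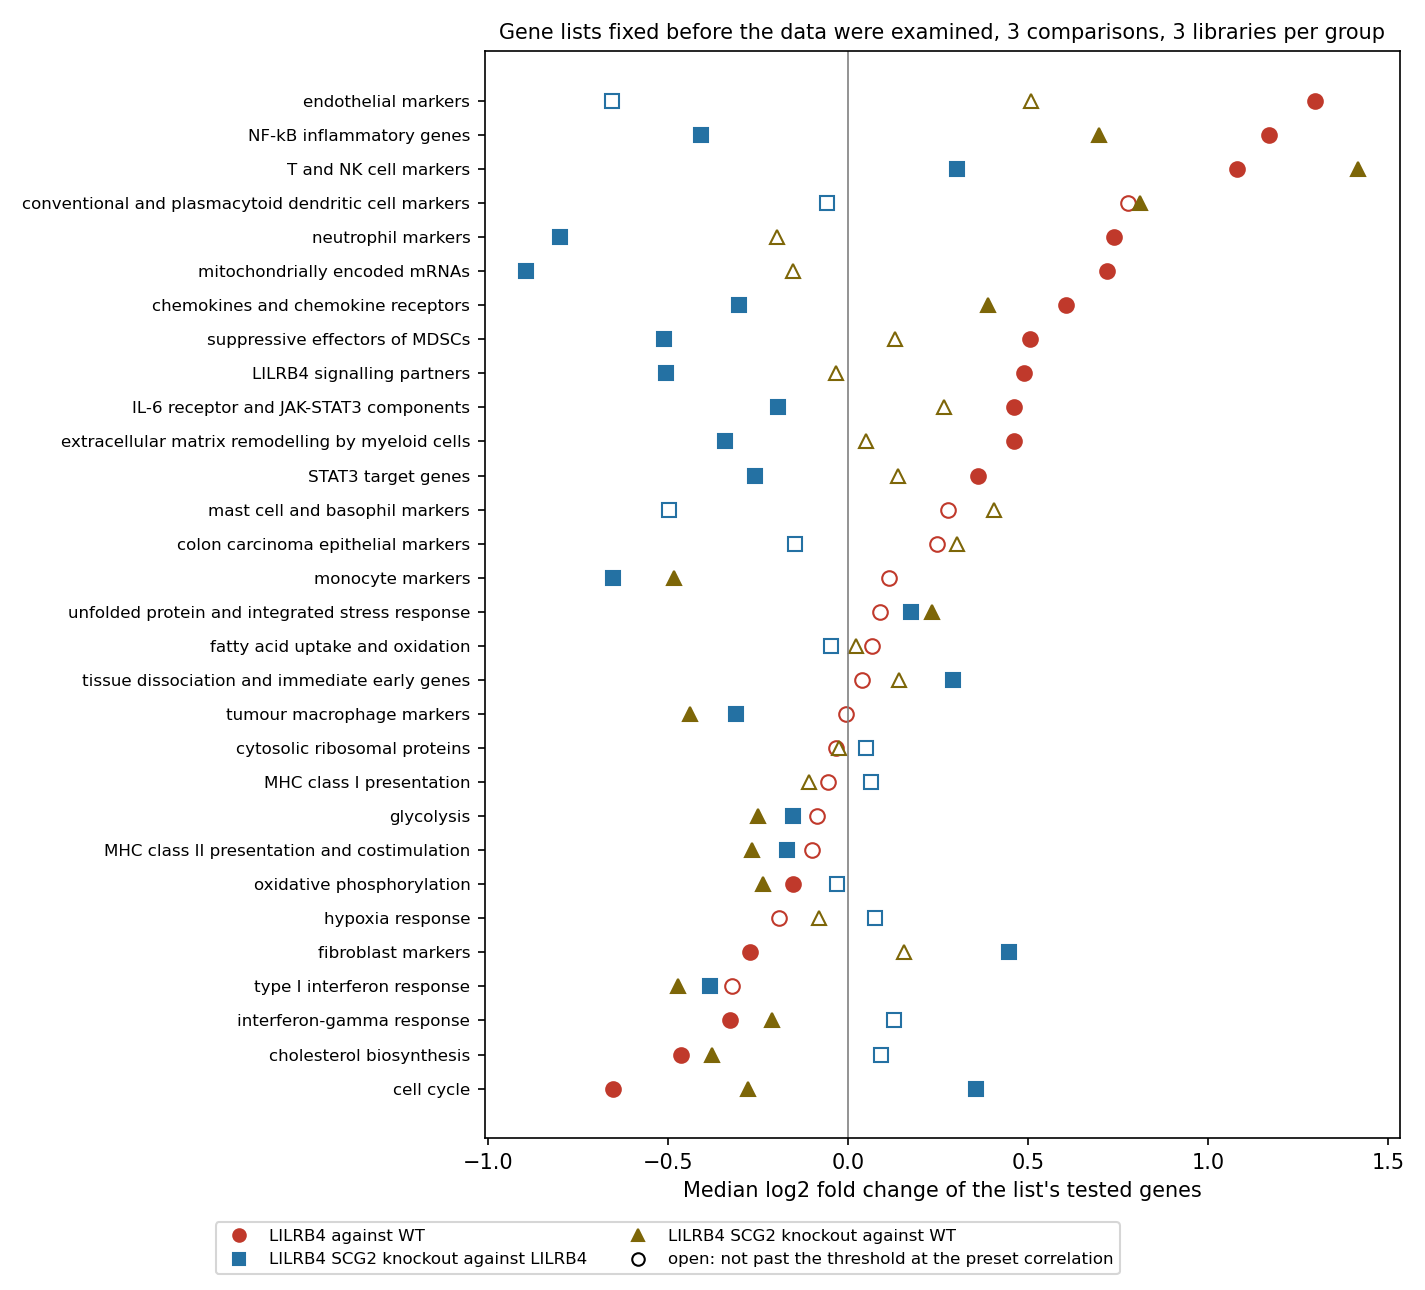
Median log2 fold change of the measured genes of 30 lists in 3 comparisons of 3 against 3 libraries, filled where camera passed at the preset correlation. NF-kB genes stood at 1.17 in LILRB4 against WT, -0.41 in SCG2 knockout against LILRB4 and 0.70 in SCG2 knockout against WT.

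SCG2 knockout against LILRB4 asks what loss of SCG2 changes on the LILRB4 background. No gene passed the test. The gene with the widest difference was Lyz2, which encodes lysozyme (chromosome 10, 117277331 to 117282321), at 20.8 ± 4.83 CPM in LILRB4, 670 ± 445 in SCG2 knockout and 90.1 ± 66.8 in WT libraries (n = 3 each; 32.1-fold, log2 SE 0.85, edgeR adjusted p = 0.222). Other genes of smallest p on the higher side were Nppb at 1.06 (SE 0.16), Enc1 at 0.86, Amotl2 at 0.79 and Ereg, an epidermal growth factor family ligand, at 0.93. On the lower side they were Kcnj2 at -1.30 (SE 0.19), Cd33, a myeloid receptor, at -1.20 (SE 0.20), Mthfsl at -1.07, St7 at -1.13 and Ptpre at -0.66. None of these 10 passed, at edgeR adjusted p of 0.204 to 0.235. Il6 stood at 168 ± 26.3 CPM in LILRB4 and 125 ± 45.2 in SCG2 knockout libraries (log2 -0.43, SE 0.24, edgeR adjusted p = 0.541) with the count table, and at 190 ± 50.7 and 120 ± 44.1 CPM (log2 -0.67) with recovered counts. Stat3 stood at -0.16 with the count table and 0.22 with recovered counts, and Arg1 at -1.02 (edgeR adjusted p = 0.249) and -0.37 (edgeR adjusted p = 0.841). Nos2 stood at -0.40 and -0.31. Socs3 at -0.55, Il6ra at -0.55, Il6st at 0.10, Lilrb4a at -0.38 and Lilr4b at -0.38 did not pass either. Of the 9877 genes 0 were higher and 0 lower with edgeR's quasi-likelihood test, while 482 were higher and 610 lower at an unadjusted p under 0.05, and DESeq2 called 12 higher and 175 lower.

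Several inflammatory and myeloid lists leaned lower in SCG2 knockout than LILRB4 libraries, with no member past the threshold over all genes. Neutrophil markers had a median log2 fold change of -0.80, with 6 of 7 members lower adjusted over the list alone, and are the 1 list whose call held with both correlations (camera adjusted p = 2.30e-11, and adjusted p = 0.0459 with an estimated correlation). With recovered counts that adjusted p was 0.197 with an estimated correlation. These 7 are the neutrophil markers held by the count table, whose rule favours genes expressed in LILRB4 libraries. Of them 2, Mmp8 and Il1r2, differ between the tables. Suppressive effectors stood at -0.51 (4 lower adjusted over the list alone; adjusted p = 0.117 with an estimated correlation). Among these 4, Arg1, S100a8 and Tgfb1 differ between the tables. Their unadjusted p by edgeR's quasi-likelihood test was 0.00218, 0.00283 and 0.00816 with the count table. With recovered counts it was 0.370, 0.0776 and 0.0296. NF-kB genes stood at -0.41 (28 of 29 negative, 5 lower adjusted over the list alone; adjusted p = 0.264 with an estimated correlation). LILRB4 signalling partners stood at -0.51 (4 lower adjusted over the list alone; adjusted p = 0.117 with an estimated correlation). The IL-6 and JAK-STAT3 list stood at -0.19 with 0 of 17 adjusted over the list alone (adjusted p = 0.178 with an estimated correlation), and STAT3 targets at -0.26 with 2 of 28 (adjusted p = 0.233 with an estimated correlation). Chemokines stood at -0.30, matrix remodelling genes at -0.34 and monocyte markers at -0.65 (4, 3 and 5 lower, and 1 monocyte marker higher, adjusted over the list alone; adjusted p = 0.256, 0.178 and 0.318 with an estimated correlation). The lower chemokine genes include Ccrl2, Ccl6 and Ccl9, which differ between the tables. Their unadjusted edgeR p was 0.000430, 0.000656 and 0.00268 with the count table, and 0.00307, 0.00589 and 0.0379 with recovered counts. Other differing genes in these counts are Il1b and Tnf (NF-kB), Arg1 (LILRB4 signalling partners), S100a8 (STAT3 targets), Mmp8 (matrix remodelling) and Cd14 (monocyte markers). Type I interferon genes stood at -0.38, MHC class II at -0.17, macrophage markers at -0.31, glycolysis at -0.15 and mitochondrially encoded mRNAs at -0.89 (adjusted p = 0.192, 0.401, 0.486, 0.497 and 0.233 with an estimated correlation). On the higher side stood cell cycle genes at 0.36 (32 of 32 positive), fibroblast markers at 0.45, T and NK cell markers at 0.30, dissociation genes at 0.29 and the unfolded protein response at 0.18 (adjusted p = 0.276, 0.276, 0.723, 0.634 and 0.538 with an estimated correlation). With other settings the macrophage median ranged from -0.62 to -0.03 and lost its call in 4 of 17. That of glycolysis ranged from -0.24 to -0.00952 and lost its call in 5 of 17. The chemokine median ranged from -0.42 to -0.13 and lost its call in 1 of 17. These 19 lists, 14 lower and 5 higher, passed camera at the preset correlation, at adjusted p of 2.30e-11 to 0.0398. The other 11 did not, and median and test differed in sign for ribosomal proteins (0.05) and dendritic cell markers (-0.06).

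SCG2 knockout against WT compares the double-altered cells with the WT background. No gene passed the test. Samd11 at 1.82 (SE 0.26), Ereg at 1.19, Pik3r1 at 0.97, Mtmr7 at 0.96 and the nuclear receptor gene Nr4a3 at 0.92 had the smallest p on the higher side. On the lower side stood the interferon-response genes Oas3 at -1.31 (SE 0.30), Dhx58 at -1.04, Zbp1 at -0.89 and Irf7 at -0.83, with Dcakd at -0.69. None of these 10 passed (edgeR adjusted p = 0.246 to 0.317). Il6 stood at 56.8 ± 9.67 CPM in WT and 125 ± 45.2 in SCG2 knockout libraries (log2 1.13, SE 0.25, edgeR adjusted p = 0.317) with the count table, and at 55.2 ± 9.97 and 120 ± 44.1 CPM (log2 1.12) with recovered counts. Stat3 stood at 0.76 and 0.98, Arg1 at -0.31 and 0.06, and Nos2 at -0.17 and -0.19 with the count table and recovered counts, and Socs3 at 0.58, Il6ra at -0.56, Il6st at 0.19, Lilrb4a at 0.76 and Lilr4b at 0.89. With edgeR's quasi-likelihood test 0 genes were higher and 0 lower of 9877, against 837 and 603 at an unadjusted p under 0.05 and 69 and 23 by DESeq2.

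Among the lists in SCG2 knockout against WT, T and NK cell markers stood highest at a median of 1.42 (22 of 22 positive), followed by dendritic cell markers at 0.81, NF-kB genes at 0.70 (15 higher adjusted over the list alone), chemokines at 0.39 and the unfolded protein response at 0.23 (2 higher adjusted over the list alone). Lower medians were those of monocyte markers at -0.48, type I interferon genes at -0.47 (11 of 27 lower adjusted over the list alone), macrophage markers at -0.44, cholesterol biosynthesis at -0.38 (3 lower adjusted over the list alone) and cell cycle genes at -0.28. MHC class II genes stood at -0.27, glycolysis at -0.25, oxidative phosphorylation at -0.24 and interferon-gamma response genes at -0.21. These 14 lists passed camera at the preset correlation, 5 higher and 9 lower, and all 14 calls were lost (adjusted p = 0.573 to 0.679 with an estimated correlation). The IL-6 and JAK-STAT3 list (median 0.27), STAT3 targets (0.14) and suppressive effectors (0.13) did not pass, with camera adjusted p of 0.0818, 0.230 and 0.258. Median and test differed in sign for LILRB4 signalling partners (-0.03) and fatty acid oxidation genes (0.02).

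**Figure D4:**
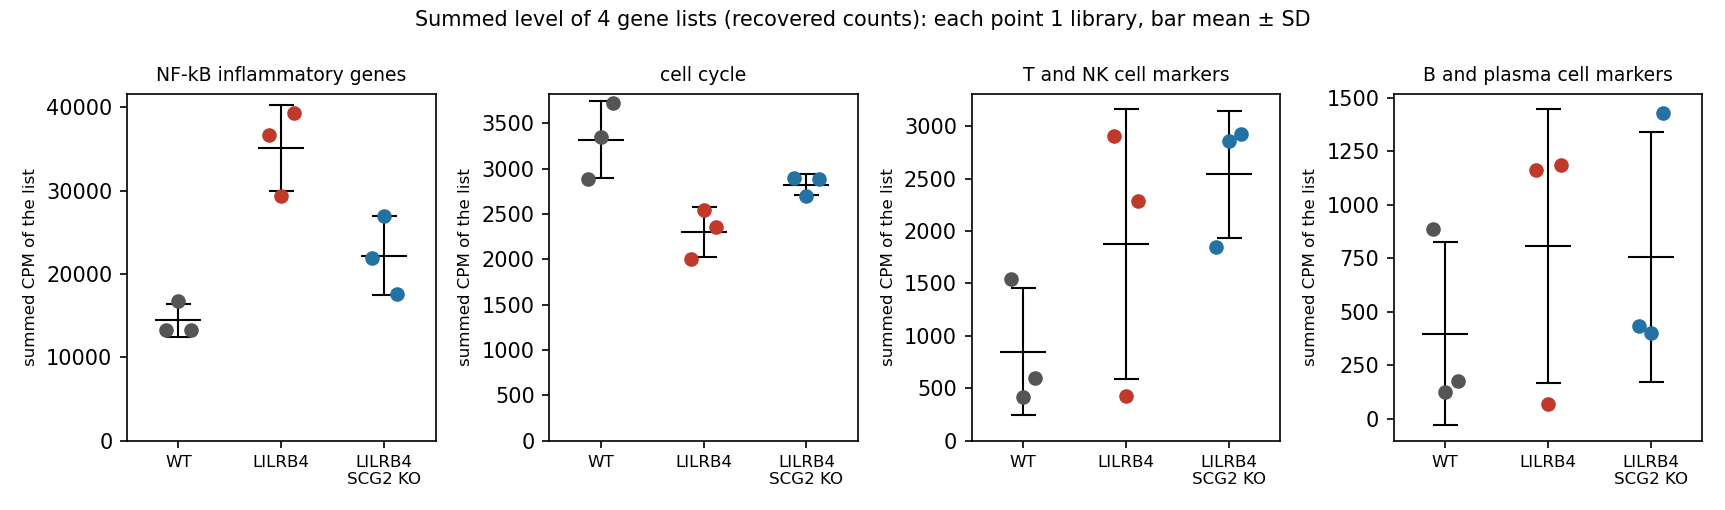
Summed CPM from recovered counts of 4 gene lists in 3 WT, 3 LILRB4 and 3 SCG2 knockout libraries, each point 1 library, with the mean and SD of each group. NF-kB genes summed to 14430 ± 1954 CPM in WT, 35100 ± 5166 in LILRB4 and 22180 ± 4714 in SCG2 knockout libraries.

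Whether loss of SCG2 turned back the LILRB4 difference was asked of genes that moved in opposite directions in LILRB4 against WT and in SCG2 knockout against LILRB4. SCG2 knockout against LILRB4 had no calls with edgeR, so no gene could be shared. DESeq2 shared 112 genes that were higher and then lower and 5 that were lower and then higher, against 10.8 and 0.379 for independent lists and a mean of 0.5 (range 0 to 2) in each direction in 20 simulations with no effect. DESeq2 was run on the count table and not on recovered counts. Of the 47 genes that differ, the count table raised the LILRB4 to WT ratio for 44 and lowered the SCG2 knockout to LILRB4 ratio for 45. That favours higher and then lower genes, and how many of the 112 are among the 47 was not counted. Both comparisons use the same LILRB4 libraries, which favours opposite signs with no effect at all. Across the 9877 genes, which are not independent replicates, the log2 fold changes correlated at -0.44, against -0.50 (range -0.51 to -0.48) in 20 simulations with no effect. The covariance was -0.0604 against -0.0346 simulated, a difference of -0.0258. With recovered counts of 15743 genes the correlation was -0.44 and the covariance -0.142, for which no simulation was made. Of genes at an unadjusted p under 0.05 in both comparisons, 99.7% had opposite signs, against 98.9% (range 95.0% to 100%) simulated, so opposite signs alone do not separate an effect from the shared libraries. Such genes with opposite signs numbered 601, against 96.9 (range 78 to 114) simulated. The simulations held the shared libraries but no effect in either comparison, so they do not give what LILRB4 effects without a reversal would give, and the excess is not taken as a shared effect. The 3 shared libraries were too few to divide, so part of the genes shared by DESeq2, beyond what independent lists would share, may come from the shared libraries.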

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

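The test on counts recovered from FPKM was chosen after the data were seen. In genes outside the deposited count table, 12 were higher in LILRB4 than WT libraries and 5 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted over 15743 genes), a difference in data that the count table does not hold. Mir155hg, the host transcript of the microRNA miR-155, stood at 7.72 ± 4.10 CPM in WT, 31.5 ± 11.4 in LILRB4 and 20.2 ± 3.37 in SCG2 knockout libraries (log2 2.03 for LILRB4 against WT, SE 0.38; mean ± SD, n = 3 each). Itgb8, an integrin subunit gene, stood at 1.30 ± 0.261, 5.16 ± 1.85 and 4.87 ± 0.654 CPM, and Dach1 at 0.860 ± 0.282, 4.99 ± 1.66 and 1.58 ± 0.444. Gm14023 (log2 2.29) overlaps Il1a and Il1bos (log2 1.74) is annotated as antisense to Il1b, so their reads are uncertain, since the strand setting of the counting is not given in the sources used here. Among the lower genes, Epha8 stood at 10.7 ± 1.56, 3.17 ± 0.723 and 4.25 ± 1.88 CPM. These genes were named after their values were seen.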

How the results depend on the processing

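The recovered counts, the omission of the 47 genes that differ between the tables and the covariate of T and NK marker level were chosen after the results were seen. The genes higher in LILRB4 than WT and those lower (171 and 51) were 612 and 312 with DESeq2, 91 and 11 with limma on log2(FPKM + 1), 86 and 11 with log2(FPKM + 0.1), and 69 and 3 with only the libraries of the 2 groups. They were 128 and 9 with recovered counts of all genes, 178 and 34 with recovered counts of the same genes and 175 and 34 without the 47 genes. With 1 library left out they ranged from 0 (WT replicate 2) to 541 (LILRB4 replicate 2) and from 0 to 148. SCG2 knockout against LILRB4 (0 and 0) gave 12 and 175 with DESeq2, 3 and 5 with the covariate, and 0 to 1 higher genes with 1 library left out, the 1 without WT replicate 1. SCG2 knockout against WT (0 and 0) gave 69 and 23 with DESeq2. Genes higher in LILRB4 and then lower in the knockout were 112 with DESeq2 and 4 with the covariate, and those lower and then higher 5 and 1. The cause of these changes was not tested. Fits with 1 library left out also had fewer libraries, though the fit without LILRB4 replicate 2 called more genes, 541 and 148.

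With the replicate number as a block, 1 gene was higher and 0 lower in LILRB4 than WT. The labels do not say whether the numbers pair the samples. Libraries with the same number had deviations correlated at 0.66, 0.54 and -0.45 between WT and LILRB4. Between LILRB4 and SCG2 knockout these were -0.54, -0.30 and -0.18, and between WT and SCG2 knockout -0.29, -0.13 and 0.41. Deviations from means of 3 libraries cannot tell whether the samples were paired.

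Gene lists past the threshold (16, 19 and 14) were 0, 1 and 0 with an estimated inter-gene correlation. A list counts as reversed where the direction of the camera test, which can differ from the sign of the median, changed and 1 of the 2 tests passed. With the covariate, the T and NK list itself went to -0.0235, 0.00468 and -0.00338 in the 3 comparisons, which follows from its construction. Macrophage markers went to 0.22 in LILRB4 against WT. In SCG2 knockout against WT, monocyte markers went to 0.0657, macrophage markers to 0.0844, dendritic cell markers to -0.22, fibroblast markers to -0.12 and endothelial markers to -0.61. With 1 library left out, SCG2 knockout against LILRB4 gave medians of -0.14 to 0.22 for ribosomal proteins (past the threshold at 0.22 without LILRB4 replicate 3 and at 0.16 without SCG2 knockout replicate 3), -0.19 to 0.11 for dendritic cell markers (past it at -0.19 without LILRB4 replicate 2) and -0.14 to 0.78 for T and NK markers (lowest without LILRB4 replicate 2, where the call was lost). NF-kB genes in LILRB4 against WT kept their direction and their side of the threshold in 16 of 17 alternatives, with medians of 0.84 to 1.43. The 1 lost was the estimated correlation. The 16 others all used the preset correlation, so they do not test that setting. The calls kept least often in LILRB4 against WT were T and NK markers (12 of 17), endothelial markers (13, 0.16 to 1.72) and oxidative phosphorylation (13, -0.24 to 0.00873). In SCG2 knockout against LILRB4 they were the unfolded protein response (11, 0.05 to 0.18), glycolysis (12), dissociation genes (12, 0.13 to 0.34), macrophage markers (13) and T and NK markers (13). In SCG2 knockout against WT they were chemokines (10, 0.12 to 0.61), interferon-gamma response (11, -0.32 to -0.09) and MHC class II (13, -0.41 to -0.00471). Oxidative phosphorylation kept its call there in 14 of 17 (-0.43 to 0.05) and glycolysis in 15 (-0.36 to -0.02). Il6 kept its call in 10 of 16 (adjusted p = 5.38e-07 to 0.125) and Socs3 in 6 of 17 (adjusted p = 0.000152 to 0.179). Self-tests recovered 16% of 1.5-fold changes, so smaller changes lie below what this depth and number of libraries show.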

Other observations

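The tests of the table differences, of NF-kB genes with recovered counts and of Lyz2 were chosen only after the result was seen. Lymphocyte transcripts varied several-fold among libraries of the same group. Summed T and NK cell markers stood at 1540, 413 and 594 CPM in the WT libraries, 2908, 429 and 2291 in LILRB4, and 1844, 2857 and 2924 in SCG2 knockout. B and plasma cell markers stood at 890, 127 and 179 CPM in WT, 1165, 68.7 and 1188 in LILRB4, and 434, 403 and 1431 in SCG2 knockout. The first principal component of the 500 most variable genes held 80.2% of their variance, with WT replicates 2 and 3 and LILRB4 replicate 2 at 32.0, 20.1 and 28.4 and the other 6 libraries at -22.4 to -2.47.

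The 2 deposited tables disagreed in 56 values of 47 genes, and the differing genes belong to the lists fixed before the data were examined more often than other genes do. Of the 47 genes 23 (48.9%) belong to at least 1 of these lists, which cover many pathways, against 5.12% of the other genes (Fisher's exact test, one-sided p = 1.55e-17). List by list, with lists that share genes, suppressive effectors held 6 (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.54e-08), matrix remodelling genes 4 (3.30e-05) and the IL-6 and JAK-STAT3 list 3 (0.000699). Chemokines, STAT3 targets and NF-kB genes held 3 each (0.00152, 0.0018 and 0.0018), neutrophil markers 2 (0.0021) and monocyte markers 2 (0.0102), while the other lists did not pass. The LILRB4 to WT ratio was higher in the count table for 44 and lower for 2, mostly through the 41 values of LILRB4 replicate 1, and the spread among LILRB4 libraries was smaller for 25 and larger for 21. The 2 lower were Il10 and Il6, at 4349 and 4376 counts in LILRB4 replicate 3 against 9349 and 6376 recovered. Their SD divided by the mean among LILRB4 libraries was 0.143 and 0.144 with the count table, and 0.486 and 0.263 with recovered counts. A second round of counting is argued against, since 97.6% of the 42 differences that are not exchanges are multiples of 100. A change of FPKM values after their denominators were set is argued against too, because the denominators matched size factors of the recovered counts to 2.08e-10%, and deviated by 0.0971% with the count table values put in. The count table values are thus the ones that depart from the quantification behind the FPKM. What stays open is how the values came to differ. The files do not say, and the read data that would settle it were not analysed here.

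NF-kB inflammatory genes stood higher in LILRB4 than WT libraries, at a median log2 fold change of 1.17. The table differences do not account for it, since recovered counts of the same genes gave 1.18 (camera adjusted p = 3.69e-30). A larger share of T and NK cells in LILRB4 libraries is argued against as the whole cause, since the median was 0.84 (camera adjusted p = 2.70e-27) with their marker level as a covariate. Both p-values are at the preset correlation, and the call is lost with an estimated one (adjusted p = 0.168 with an estimated correlation). A genotype difference between the mice may contribute and stays open, as does a difference between animals or days, which the labels do not record.

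Lyz2 stood at 333, 2505 and 2946 counts in the WT libraries, 247, 582 and 579 in LILRB4, and 20434, 7713 and 5451 in SCG2 knockout, and did not pass the test. Reads shared with its neighbour Lyz1 are argued against, since Lyz1 and Lyz2 together had a log2 ratio of 3.75 between SCG2 knockout and LILRB4. More monocytes and macrophages are argued against by the 36 other markers of these cells in the count table, with a median log2 fold change of -0.50. The rule of that table favours genes expressed in LILRB4 libraries, which may lower this median, so this cause is not excluded. The 13 neighbouring genes had log2 fold changes of -0.62 (Lyz1) to 0.18 (Nup107) in this comparison. A difference between the mice at Lyz2 may be a source, which these values do not test.

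Splits of the same libraries were counted, with the real split included in each number. For LILRB4 against WT, 2 of the 10 splits of the 6 libraries gave as many genes as the real 222, and the highest other gave 517. That split set WT replicate 1 and LILRB4 replicates 1 and 3 against the other 3 libraries, it follows the T and NK marker level, and it points to a structure of the samples. For gene lists 5 of 10 splits gave at least the real 16, with a highest other of 18. In SCG2 knockout against LILRB4, 10 of 10 splits gave at least the real 0 genes (highest other 0) and 3 of 10 at least the real 19 lists (highest other 21). In SCG2 knockout against WT these were 10 of 10 for 0 genes (highest other 0) and 5 of 10 for 14 lists (highest other 21). Any split gives at least 0 genes, so the 10 of 10 for genes was fixed in advance in both comparisons. Splits of 6 libraries number 10, too few for a share under 0.05.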
